A study of Homo sapiens with 57 samples.

How the data were processed

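The study used BJ-hTERT cells, a line of human foreskin fibroblasts immortalised with telomerase, that carry a B-RAF-V600E oncogene switched on by doxycycline. RNA was labelled for Illumina expression BeadChips, per the labels' protocols, and 57 arrays in 14 groups were deposited. Each group held 3 to 8 arrays. The labels do not say whether arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

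Values came from the series' deposited table of probe intensities on a linear scale. How the authors made these intensities is not given in the sources used here. Column medians ran from 126.203 to 126.204, and after sorting each column the largest ratio between columns at any rank was 1.00087. All columns thus shared 1 distribution, as after quantile normalization, and no background had been subtracted, since the lowest value was 88.6. Intensities were used without centring. A table of non-normalized signals was not used here, because its 57 signal columns and 57 detection p-value columns carry only chip positions that match no sample's labels. For that reason the planned background correction from those signals, the filter on detection p-values and the chip as a block could not be applied, and the log2 of the quantile-normalized intensities became the main values.

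A background level was read from the shared distribution, whose mode was 118 intensity units. The limit was set 3 SD of the values below the mode above it, at an intensity of 143 or 7.16 on the log2 scale. Probes above this limit on at least 3 arrays were tested, which were 22244 of 48107. Because the background stays in the values, log2 changes understate the change of dim probes. Where every array of the dimmer group lay at or below the limit, a change is given as at least N-fold, from the brighter group's mean against the dimmer group's mean with each array set to the higher of the limit and its own value.

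Probe identifiers were checked before gene names were attached. The annotation gave 1 gene symbol for 30113 rows, several for 8 and none for 17986. Of 16 genes with abundant transcripts in fibroblasts, chosen after the values were first seen, 14 had a probe. Their 26 probes were above the background level in 11 cases, or 42.3%, against 34.5% of the other 30087 named probes (Fisher's exact test, p = 0.414). Probes for EEF1A1, which encodes a translation elongation factor, had mean log2 intensities of 6.86, 7.08, 6.78 and 8.25, and the probe for the collagen gene COL1A1 had 6.86. Those for ACTB, which encodes actin, had 11.90, 10.07 and 6.94. Across 14956 pairs of probes annotated to the same gene, the mean levels correlated with r = -0.0087, inside the range of -0.015 to 0.016 that held 95% of 1000 random relabelings. Shifting the identifiers by up to 1500 rows gave no correlation above 0.030. In the table as used here the identifiers, read through the annotation, therefore do not name the probe whose value stands beside them. Whether the fault lies in the table or in the annotation was not tested. Gene symbols, the rule for naming genes, the selection of 1 probe per gene, the removal of control rows and the check of the induced oncogene's own probes were not used, and rows are treated as unnamed probes. Among 304 tests of 16 gene lists in 19 comparisons through these identifiers (camera), 7 had an unadjusted p under 0.05 and 0 passed after Benjamini-Hochberg adjustment within a comparison. These list tests say nothing about the pathways.

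The model was a limma 3.58.1 linear model in R 4.3.3 with a mean for each of the 14 groups and moderated variances with a trend. All 57 arrays shared 1 estimate of the spread. A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Adjusted p-values below are limma's. A moderated F test asked whether the clobetasol change differed among the 5 states in which it was measured. Probe sets were tested with fry, which asks whether a set's probes move one way on balance, with p-values adjusted over the 30 set tests run, and per-array set means were compared with exact two-sided permutation tests. These permutations ignore any pairing of arrays by number. The set of the RAF programme was fixed before the data were examined as probes changed at least 2-fold at 74 h. A set of clobetasol probes and a set of Compound A probes were chosen after seeing the data. The naming rule took the 8 largest rises and the 8 largest falls among changed probes of each comparison; with names unusable, at most 2 rows of each direction are given by their deposited identifier.

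The model was tested on simulated data built from the group means and residual spreads of the 22244 probes, with 100 probes changed by 0.5 and 100 by 1 on the log2 scale. For the clobetasol comparison at 74 h, 96% of the smaller and 100% of the larger changes were recovered with 13 false calls. For long clobetasol at 122 h the shares were 92% and 98%, with 8 false calls, for Compound A at 26 h 89% and 100%, with 5, and for RAF induction with long clobetasol in both arms 82% and 100%, with 3. The simulated noise was independent between probes and equal between groups. In the real arrays 1 shared component held 28.0% of the within-group variance. No simulated comparison used the uninduced DMSO arrays, so these false calls do not measure those in the real data. Array numbers were taken as pairing the arrays where the within-group deviations of every same-numbered pair correlated above 0.1. This held for RAF induction at 122 h (0.12 to 0.27), clobetasol at 122 h (0.18 to 0.52), Compound A in uninduced cells (0.14 to 0.36) and Compound A at 26 h (0.19 to 0.62). The labels do not say what the numbers mark. No array pair of a group was near-identical: the root mean square difference between arrays of a group ran from 0.11 to 0.35 on the log2 scale over 97 pairs.

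Alternatives covered an added constant of 16, no filter, variances without a trend, array weights, a replicate block, only the groups compared, a minimum change of 1.5-fold and leaving out each array. Alternatives added after seeing the data were normexp with an offset of 50, a filter on more arrays, a replicate block within the groups compared, leaving out each pair of uninduced DMSO arrays, and choosing the RAF set on 2 of them with the other 2 as the baseline of its score.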

Results

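Gene expression was measured on 57 BeadChip arrays of BJ-hTERT fibroblasts with doxycycline-inducible B-RAF-V600E. Induced cells received doxycycline at 1000 ng/mL and were harvested after 26, 50, 74 or 122 h. During the last 2 h they received the glucocorticoid clobetasol at 2 nM, Compound A at 2 µM, or the DMSO vehicle. Uninduced cells, labelled EtOH in place of doxycycline, received the 3 short treatments at 26 h. Clobetasol was also present for the full 122 h in an induced and an uninduced group. Groups held 4 arrays, except clobetasol at 26 h of induction with 8, and Compound A at 26 h of induction and both long clobetasol groups with 3 each. The only uninduced DMSO arrays were at 26 h, so comparisons of later times with them also differ in time. No group had doxycycline without the inducible oncogene, so effects of doxycycline itself cannot be told apart from those of RAF. Read through the annotation, the probe identifiers did not name the probes whose values stand beside them, and the results describe unnamed probes.

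RAF induction, the comparison of doxycycline-treated with uninduced cells under DMSO, changed 6927 of 22244 tested probes at 26 h. At 50 h it changed 11563, at 74 h 11137 and at 122 h 10302. Rises and falls were near equal in number, with 5461 raised and 5676 lowered at 74 h. The distribution shared by all arrays favours such a balance, and a shift of most probes 1 way could not be seen. Changes of at least 2-fold were fewer, with 297 raised and 303 lowered at 26 h, and 865 raised and 934 lowered at 74 h. Across all 4 times 1668 probes were raised and 1985 were lowered. The largest rise at 122 h was from a log2 intensity of 7.88 ± 0.93 (SD, n = 4) to 14.67 ± 0.063 (SD, n = 4), a log2 change of 6.79 (SE 0.19, limma adjusted p = 8.16e-36). That probe was above background on 3 of the 4 uninduced arrays. Another probe lay at background on all 4 uninduced arrays and was at least 81.2-fold higher at 122 h. The largest fall at 122 h was from 14.22 ± 0.44 (SD, n = 4) to 8.88 ± 0.096 (SD, n = 4), a log2 change of -5.34 (SE 0.12, limma adjusted p = 5.03e-40). With only these groups in the fit, 4523 probes changed at 26 h.

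The changes at 74 h and at the other times correlated across probes, which are not independent replicates. The correlation was 0.596 with 26 h, 0.885 with 50 h and 0.901 with 122 h. All these comparisons share the uninduced arrays, and simulated groups with no change gave 0.50. The simulation gave every group the same spread. The real uninduced DMSO arrays differed more, by a median of 0.33 in root mean square log2 difference against 0.18 over all groups. A value with no change would thus lie above 0.50, and the 0.596 cannot be read as exceeding it. With the controls split into separate pairs the correlation ranged from 0.327 to 0.589, from 0.767 to 0.877 and from 0.765 to 0.892. Such pairs share no arrays, so these values argue against shared uninduced arrays as the sole source of the correlations. The covariances were 0.136, 0.323 and 0.326, against 0.0044 in the simulation. At both 74 h and 122 h, 3828 probes were raised and 4203 lowered, in lists that share the uninduced arrays.

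**Figure D1:**
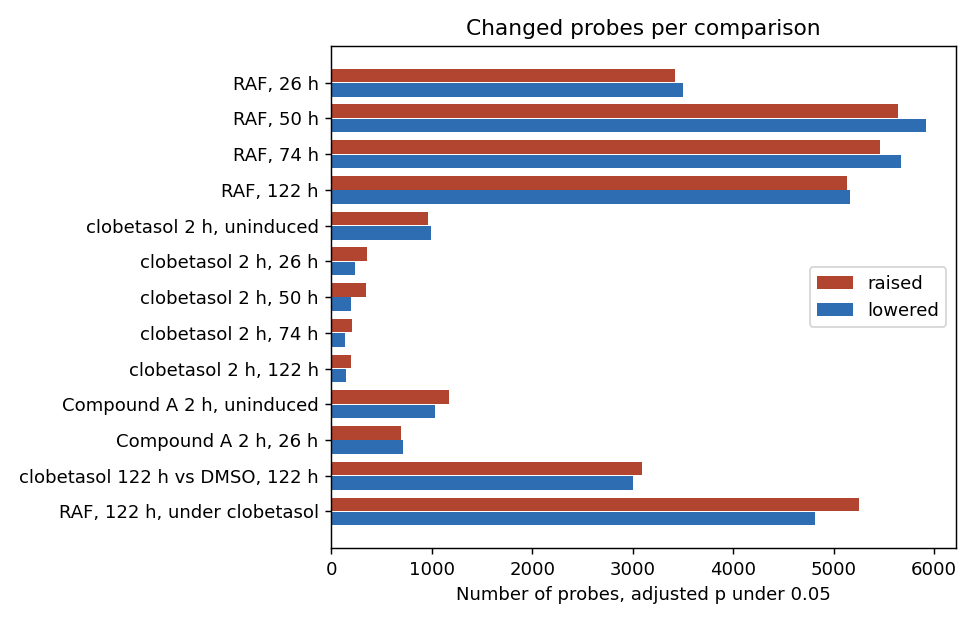
Number of probes raised (red) or lowered (blue) at an adjusted p under 0.05, on the horizontal axis, for 13 comparisons on the vertical axis. RAF induction at 74 h changed 11137 probes and clobetasol for 2 h at that time 336.

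Clobetasol for 2 h, compared with DMSO in each state, changed 586 probes at 26 h of induction, 544 at 50 h, 336 at 74 h and 340 at 122 h. In uninduced cells it changed 1955. Raised probes outnumbered lowered ones in the induced states, with 351 against 235 at 26 h and 203 against 133 at 74 h. In uninduced cells 958 were raised and 997 lowered. At least 2-fold changes were 30 rises and 7 falls at 74 h, and 46 rises and 60 falls in uninduced cells. In all 5 states 76 probes were raised and 23 lowered. At 50 h and 74 h together, which share no arrays, 151 probes were raised and 81 lowered, where independent lists would share 3.16 and 1.18. The mean change over the 5 states was past the threshold for 842 raised and 666 lowered probes. In both directions together these were 1508, and 3407 without uninduced DMSO replicates 1 and 4. Without replicate 3 of clobetasol at 50 h, 833 probes changed at that time. With only the groups compared, 355 changed at 50 h. With a replicate block within the groups compared, 388 changed at 26 h and 286 at 50 h. The 8 clobetasol arrays at 26 h formed 2 clusters, and setting replicates 2, 3, 6 and 8 with the DMSO arrays gave 1208 changed probes there.

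The row deposited as ILMN_1752416, a label that does not name its gene here, had the largest mean rise over the 5 states, a log2 change of 3.34 (SE 0.070, limma adjusted p = 1.69e-40). Its mean log2 intensity at 26 h of induction was 12.57 ± 0.15 (SD, n = 8) with clobetasol and 7.98 ± 0.11 (SD, n = 4) with DMSO. The row deposited as ILMN_1685531 followed, with a mean rise of 3.08 (SE 0.11). It rose by 4.91 at 74 h (SE 0.25, limma adjusted p = 1.48e-21) and by 1.32 at 26 h (SE 0.22). With clobetasol its mean log2 intensity was 12.16 ± 0.66 (SD, n = 8) at 26 h and 12.34 ± 0.11 (SD, n = 4) at 74 h. With DMSO it was 10.83 ± 0.15 (SD, n = 4) and 7.44 ± 0.17 (SD, n = 4), so the rises differed mainly in the DMSO level. In uninduced cells its change was 0.74 (SE 0.25, limma adjusted p = 0.0568), which did not pass the threshold. The largest mean falls were in the rows deposited as ILMN_1730491, at -1.30 (SE 0.049), and ILMN_1682606, at -1.21 (SE 0.064). The largest fall at 74 h was 3.05-fold and the largest rise 30.0-fold.

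The count in uninduced cells rested on the DMSO arrays. It was 3522 without DMSO replicate 1, 548 without replicate 2, 548 without replicate 3, 3282 without replicate 4, and 1228 without clobetasol replicate 3. With only the groups compared it was 145, and 6 of 35 splits of the arrays, the real one included, gave as many as the real 1955. The 4 uninduced DMSO arrays lay apart from each other by up to 0.35 in root mean square log2 difference. Replicates 1 and 4 lay 0.19 and 0.20 from the uninduced clobetasol arrays on average and 0.34 and 0.33 from the Compound A arrays. Replicates 2 and 3 lay 0.36 and 0.36 from the clobetasol arrays and 0.20 and 0.21 from the Compound A arrays.

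**Figure D2:**
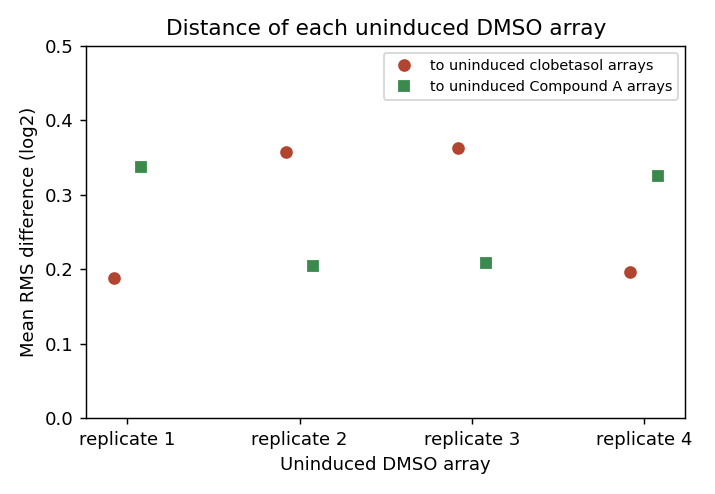
Mean root mean square log2 difference across tested probes (vertical axis) from each of the 4 uninduced DMSO arrays (horizontal axis) to the 4 uninduced clobetasol arrays (circles) and the 4 uninduced Compound A arrays (squares). Replicate 1 lay 0.19 from the former and 0.34 from the latter, and replicate 2 lay 0.36 and 0.20.

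Whether the clobetasol response depended on RAF was tested directly. The mean change in the 4 induced states differed from that in uninduced cells for 1146 probes, 649 higher and 497 lower, but 20 of 100 drawings of the drug labels within states, the real one included, gave as many, so chance cannot be excluded for this count. The F test over the 5 states called 402 probes, 1.81% of those tested. The first count was 2700, 170, 182 and 2483 without uninduced DMSO replicates 1, 2, 3 and 4, and 694 and 598 without uninduced clobetasol replicates 3 and 4. The F test called 1554 without DMSO replicate 1 and 1348 without replicate 4.

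A set of 23 probes raised at least 2-fold by clobetasol at both 50 h and 74 h was read on the other arrays. All 23 were higher with clobetasol at 26 h, and all 23 passed the threshold. The set mean was 10.81 ± 0.14 (SD, n = 8) with clobetasol and 9.14 ± 0.036 (SD, n = 4) with DMSO (exact permutation p = 0.00404, the smallest this design allows). In uninduced cells it was 10.77 ± 0.052 (SD, n = 4) with clobetasol and 9.50 ± 0.10 (SD, n = 4) with DMSO, with 20 of 23 probes past the threshold (exact permutation p = 0.0286, the smallest possible). At 26 h of induction the 8 clobetasol arrays lay in the 2 clusters named above, at 10.66 to 10.72 and at 10.91 to 10.96. The permutation tests that use these 8 arrays, here and against Compound A, treat them as exchangeable.

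Compound A, tested at 2 µM against clobetasol at 2 nM, changed 1408 probes at 26 h of induction, 691 raised and 717 lowered. The doses of both compounds differ. In uninduced cells it changed 2204 probes, 1168 raised and 1036 lowered. Its set mean of the clobetasol probes at 26 h was 9.25 ± 0.018 (SD, n = 3), 0.11 above DMSO with a 95% interval of -0.040 to 0.26 from the pooled spread of the arrays (exact permutation p = 0.0571, the smallest this design allows). Against clobetasol the mean was lower by 1.56, with an interval of -1.70 to -1.43 for the difference (exact permutation p = 0.0121, the smallest possible). In uninduced cells the set mean differed from DMSO by -0.012, with an interval of -0.15 to 0.13 (exact permutation p = 0.80). Of the 23 probes, 6 rose and 5 fell past the threshold with Compound A at 26 h, where 6.33% of all tested probes changed. A set mean near DMSO thus does not mean that no probe of the set responded. Of the rows named above, ILMN_1752416 rose by 0.93 (limma adjusted p = 0.00017). ILMN_1730491 fell by a log2 change of -0.94 (limma adjusted p = 6.61e-08). ILMN_1685531 and ILMN_1682606 did not pass the threshold.

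The arrays of both compounds differed in 1731 probes at 26 h and in 6609 in uninduced cells. Across probes the uninduced difference correlated with the leading component among the 4 uninduced DMSO arrays (r = 0.787), which had no part in it, so the 6609 cannot be assigned to the compounds alone. A set of 62 probes raised at least 2-fold by Compound A at 26 h was also higher with it in uninduced cells. The mean difference was 0.67, with an exact permutation p of 0.0286, the smallest possible, which ignores the pairing of these arrays by number. In uninduced cells 41 of the 62 passed the threshold. The set of 23 lowered probes was lower by a mean log2 change of -0.84 there, with 18 past the threshold. The DMSO arrays lay apart on both sets. For replicates 1 to 4 the means were 9.67, 9.11, 9.07 and 9.62 on the lowered set, and 9.78, 9.41, 9.38 and 9.80 on the raised set. The median change of the lowered set was -0.56 without replicates 1 and 4 and -1.11 without 2 and 3. That of the raised set was 0.84 and 0.64. The Compound A count at 26 h was 933 and 893 without its replicates 1 and 2, and 2925 with a replicate block within the groups compared. The difference from clobetasol at 26 h was 957 and 1101 without those replicates. The uninduced count was 1232 and 1251 without DMSO replicates 1 and 4, 395 with only the groups compared, and 514 with a replicate block within them. The clobetasol arrays at 26 h also lay apart on both Compound A sets, by the clusters named above. On the raised set the cluster with replicate 1 lay at 9.56 to 9.63 and the other at 9.24 to 9.26. On the lowered set they lay at 9.43 to 9.48 and at 9.79 to 9.82. The Compound A means there were 10.67 and 8.63, so the cluster with replicate 1 lay nearer to them. How much of the 1731 rests on this division was not tested.

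**Figure D3:**
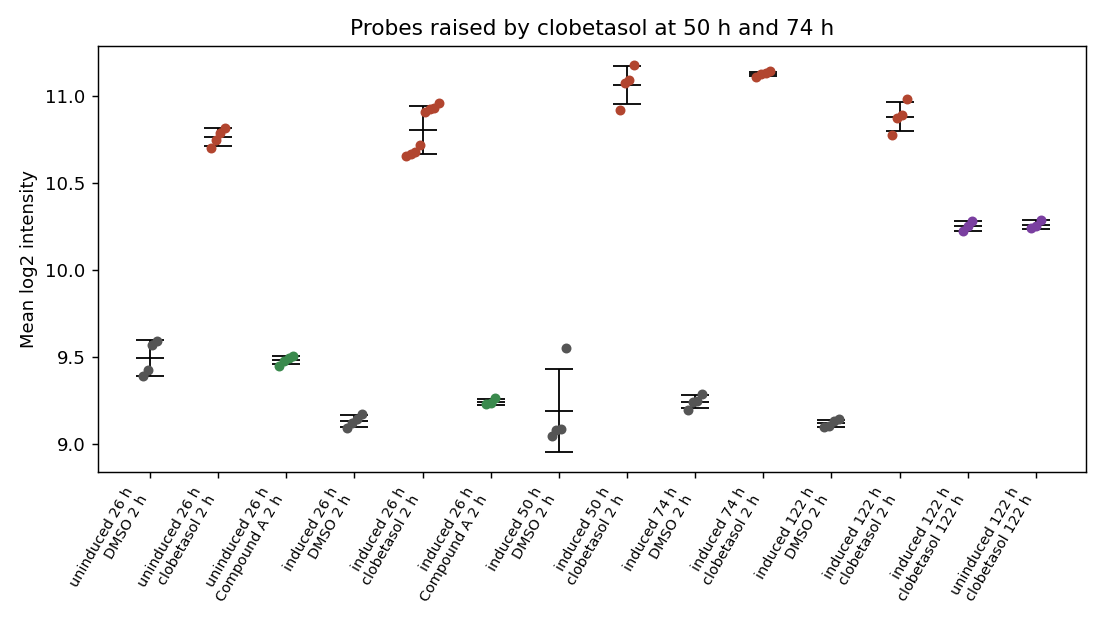
Mean log2 intensity (vertical axis) of the 23 probes raised at least 2-fold by clobetasol at 50 h and 74 h, for each array (points) by group (horizontal axis), with mean and SD (bars). DMSO and Compound A arrays lay at or below 9.60 and all clobetasol arrays at or above 10.2; the set was chosen on the arrays at 50 h and 74 h.

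Long clobetasol, present for all 122 h of induction, addressed whether the drug altered the response to RAF. No group had DMSO for 122 h, so against DMSO the length of treatment differs along with the drug. Against DMSO at 122 h long clobetasol changed 6096 probes, 3093 raised and 3003 lowered, of which 156 and 285 changed at least 2-fold. Against clobetasol for 2 h it changed 5931 probes, and 2116 with a replicate block within the groups compared. The largest fall against DMSO was from 12.25 ± 0.10 (SD, n = 4) to 7.62 ± 0.086 (SD, n = 3), a log2 change of -4.62 (SE 0.15, limma adjusted p = 1.92e-31). A probe at background on all 4 DMSO arrays was at least 11.6-fold higher. The clobetasol set mean after 122 h was 10.25 ± 0.031 (SD, n = 3), 1.13 above DMSO (exact permutation p = 0.0571, the smallest this design allows) and 0.63 below clobetasol for 2 h, a difference with an interval of -0.78 to -0.48. With both arms in clobetasol for 122 h, RAF induction changed 10072 probes, 5252 raised and 4820 lowered. Of these, 819 were raised and 997 lowered at least 2-fold. With DMSO at 122 h, against uninduced cells at 26 h, such rises were 768 and such falls 870. Uninduced cells with clobetasol for 122 h differed from uninduced DMSO cells at 26 h in 9828 probes, and in 5953 with such a block, a comparison in which time differs too. The 10302 probes of RAF induction at 122 h were counted against the same DMSO arrays, with the same difference in time.

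The RAF programme, the 865 raised and 934 lowered probes of the comparison at 74 h, was read at 122 h. Its raised probes were 0.23 lower on average with long clobetasol than with DMSO given for 2 h (limma's fry, adjusted p = 3.66e-12). Of the 865 raised probes, 375 were lowered and 196 higher past the threshold. Against clobetasol for 2 h the raised probes were lower too (limma's fry, adjusted p = 1.68e-09). The lowered probes differed from DMSO by 0.034 on average, with an interval of -0.044 to 0.11 (limma's fry, adjusted p = 0.289). The score, the mean of raised minus lowered probes, was 1.67 ± 0.025 (SD, n = 4) with DMSO, 1.59 ± 0.022 (SD, n = 4) with clobetasol for 2 h and 1.40 ± 0.069 (SD, n = 3) with long clobetasol. Long clobetasol and DMSO differed by -0.26 (exact two-sided permutation p = 0.0571, the smallest 35 splits allow), which was -8.94% of the rise from uninduced DMSO cells at 26 h. With long clobetasol in both arms the score rose by 2.31, against 2.94 with DMSO, which is 21.5% less. The set was chosen against the same uninduced DMSO arrays, which favours the larger rise. Using 2 of those arrays to choose the set and the other 2 as the baseline was tried after seeing the data. The rise was then 12.1% to 21.3% less over the 6 pairs, least with replicates 1 and 4 as the baseline. Every such set was still chosen on the response with DMSO at 74 h, which favours DMSO here and in the comparisons with DMSO above. No set chosen with clobetasol in both arms was tried, so a weaker response to RAF under clobetasol is not established. With all 4 arrays the raised probes rose by 1.14 against 1.38 and the lowered probes fell by a mean log2 change of -1.17 against -1.56. The uninduced cells scored -0.90 ± 0.022 (SD, n = 3) with long clobetasol and -1.27 ± 0.29 (SD, n = 4) with DMSO, and these groups differ in time too. Clobetasol for 2 h and DMSO differed by -0.078 (exact two-sided permutation p = 0.0286, the smallest possible). This test ignores the pairing of these arrays by number, under which 4 pairs allow no exact two-sided p under 0.05. Between clobetasol for 2 h and DMSO the raised probes of the set had an unadjusted limma fry p of 0.0479 and an adjusted p of 0.0598. The unadjusted p was 0.110 and 0.146 without clobetasol replicates 1 and 3, 0.0506 and 0.172 without DMSO replicates 3 and 4, and 0.0538 with a replicate block.

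**Figure D4:**
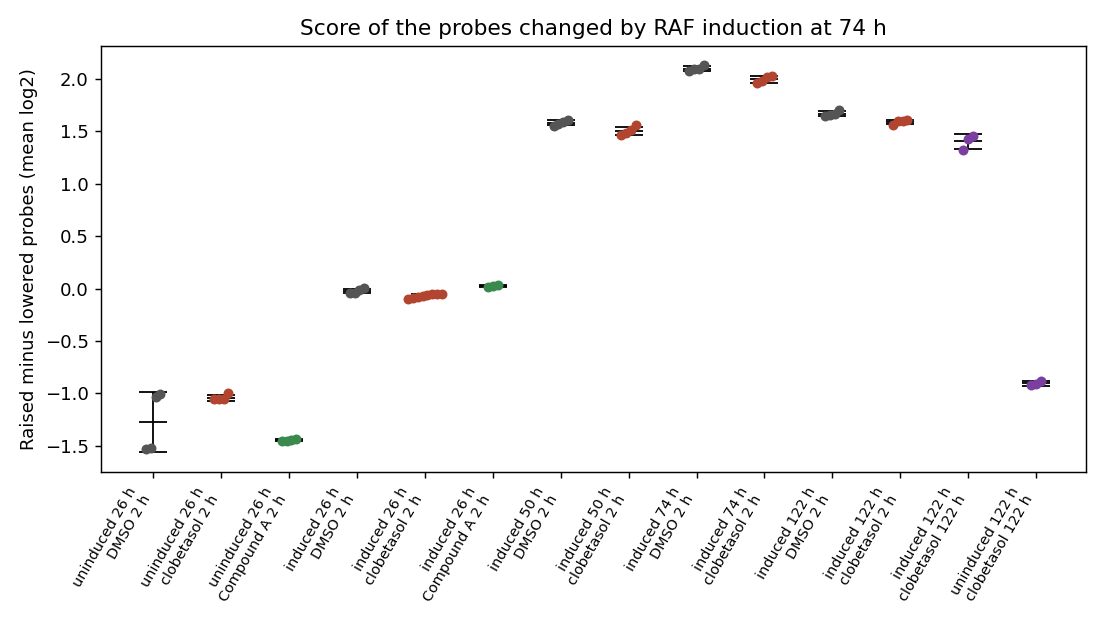
Score of the RAF programme (vertical axis, mean log2 intensity of 865 raised minus 934 lowered probes) for each array (points) by group (horizontal axis), with mean and SD (bars). At 122 h of induction the group means were 1.67 with DMSO, 1.59 with clobetasol for 2 h and 1.40 with clobetasol for 122 h; the set was chosen on the arrays at 74 h and the uninduced DMSO arrays.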

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

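The tests of the identifiers, of the uninduced DMSO arrays and of the DMSO array at 50 h were chosen after the results were seen; the counts of splits were planned before the data were examined, except that for the F test over the states, written down after its count of drawings had been seen. In 66 checks of a group of arrays on a score or a probe, an array stood apart from the rest of its group in 4. These fall on 3 arrays. Chance gives about 1 in 20 such checks, so their number alone is near what chance gives.

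Of 26 probes annotated to abundant genes, 11 lay above background, where such genes are expected to, the pattern that kept gene names out of the results. Arrays without signal are argued against by the median correlation of 0.994 across probes between arrays of a group. A constant displacement of the rows is argued against by the highest correlation of 0.030 between same-gene probes over 3000 shifts. Same-gene probes correlated in level with r = -0.0087, as random names would, so a candidate explanation is that the order of the identifiers and that of the values parted before deposit or in a later copy. No biological explanation was tested. A fault of the annotation was not tested apart from one of the table, and where the order was lost stays open.

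The clobetasol set mean of replicate 2 among the DMSO arrays at 50 h was 9.55, apart from 9.09 for the next and 9.05 for the lowest, and its log2 intensity for the row ILMN_1685531 was 9.57 against 8.02 and 7.78. Over 183 probes outside the clobetasol sets that changed at both 74 h and 122 h, its deviation from its group correlated with the clobetasol change at r = 0.534, above the -0.18 to 0.17 of 7 other DMSO arrays by slightly more than their range of 0.35, which argues against array noise. Over 21 probes raised at least 2-fold at 74 h and 122 h, a mislabelled clobetasol array is argued against by the upper quartile of 12.5% of the linear clobetasol rise at 50 h. The median was 10.9% with an interquartile range of 3.69 percentage points, so admixture of RNA from a clobetasol-treated culture is a candidate explanation. Single raised probes ran from -5.03% to 30.3%. An admixture would give lowered probes a like share, but 5 lowered probes gave a median of 27.6%, which does not go with it. A weak exposure of the array's own culture to clobetasol was not tested and stays open.

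The RAF score of replicate 4 among the uninduced clobetasol arrays was -0.998, apart from -1.05 for the next and -1.06 for the lowest. The log2 intensity of the row ILMN_1730491 was 9.83 in replicate 3 of DMSO at 26 h of induction, apart from 9.58 and 9.54.

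The clobetasol change differed between induced and uninduced cells for 1146 probes, by a test of the difference itself. Of 100 drawings of the drug labels within each state, the real one included, 20 gave as many, with a highest other count of 1850, so chance cannot be excluded for this count. The F test over the 5 states called 402 probes, and 4 of 100 drawings gave as many, with a highest other count of 847, a share under 0.05 by a margin too small for 100 drawings to settle whether chance is excluded.

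The 4 uninduced DMSO arrays lay apart from each other, and both counts above and the counts of either compound against DMSO in uninduced cells rest on them. Mislabelled clobetasol arrays are argued against by a gap of 1.11 on the clobetasol set between the highest DMSO array at 9.60 and the lowest clobetasol array at 10.70. Mislabelled Compound A arrays are argued against by a gap of 0.44 on the probes raised by Compound A at 26 h. The leading component of the 4 arrays held 77.9% of their variance and correlated across probes with the Compound A minus clobetasol difference in uninduced cells (r = 0.787), and with that at 26 h of induction at r = -0.062, so a preparation difference shared with the treated uninduced arrays may be the source. Chip and preparation day were not used here, and which arrays shared them stays open.

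Other splits of the same arrays gave the following. For RAF induction the real split was the only 1 of 35 with as many probes. The highest other counts were 3016 at 26 h, 5770 at 50 h, 5936 at 74 h and 5613 at 122 h. This share is under 0.05, with no allowance for the number of comparisons or for pairing by array number. For clobetasol at 50 h, 74 h and 122 h the real split was also 1 of 35, with highest other counts of 402, 29 and 86. At 26 h, 2 of 100 drawn splits gave as many as the real 586, with a highest other count of 1208 for a split that set clobetasol replicates 2, 3, 6 and 8 with the DMSO arrays. In uninduced cells 6 of 35 splits gave as many as the real 1955, with a highest other count of 2695, so chance cannot be excluded there. For the mean over states it was 1 of 100, with a highest other count of 325.

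For Compound A it was 1 of 35 in uninduced cells and at 26 h, with highest other counts of 1668 and 1166. Against clobetasol it was 1 of 35 in uninduced cells, with a highest other count of 2156, and 1 of 100 at 26 h, with 635. For long clobetasol against DMSO and against 2 h of clobetasol it was 1 of 35, with 3732 and 4044, and for uninduced cells 1 of 35 with 7824. Each share is under 0.05, with no allowance for the number of comparisons or for pairing by array number. The 1408 for Compound A at 26 h became 933 and 893 without its replicates 1 and 2. In uninduced cells the 2204 for Compound A rests on the divided DMSO arrays. The 6609 between both compounds there may hold the preparation difference named above (r = 0.787). The count between both compounds at 26 h may hold the difference between the clusters of clobetasol arrays, which was not tested. RAF induction with both arms in long clobetasol allows 10 splits, too few for a share under 0.05: the real count was 10072 and the highest other 1. Where the array numbers paired the arrays, 7 other splits parted every pair, and the highest of their counts was 4635 for RAF at 122 h, 1 for clobetasol at 122 h, 920 for Compound A in uninduced cells and 329 at 26 h. Each of those splits sets arrays of both treatments in at least 1 arm. They are too few for a share under 0.05, as are the 10 splits above.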

How the results depend on the processing

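The added settings named in the methods, normexp, the filter on more arrays, the block within the groups compared and the pairs of DMSO arrays left out, were chosen after seeing the data. Signal over background limits small changes of dim probes. Set tests are judged here on fry's unadjusted p. The added constant, no filter, variances without a trend and the filter on more arrays left every count within 1.5 times and every set test on its side of 0.05, as a RAF set defined at 50 h did for the 10 RAF set tests. Not run were the chip as a block, all probes of a gene, detection p-values and an estimated correlation for gene lists. The causes of the shifts below were not tested, unless named.

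At a minimum of 1.5-fold, which lowers each count by construction, RAF induction changed 1750, 4092, 4079 and 3651 probes from 26 h to 122 h, and 4074 under long clobetasol. Clobetasol changed 397 in uninduced cells and 142, 170, 134 and 140 in induced cells, 119 on average and 307 by RAF state. Compound A changed 350 and 278, and differed from clobetasol in 1395 and 283. Long clobetasol changed 1519 against DMSO, 1400 against 2 h and 3275 in uninduced cells. With array weights, whose fit stopped before convergence, Compound A changed 1111 and 2892, differed from clobetasol at 26 h in 3364, and the F test called 899. The raised RAF set under clobetasol for 2 h did not pass after adjustment, and its unadjusted p of 0.0479 became 0.0644 with array weights, 0.0828 with normexp and 0.0538 with the replicate block, at medians of -0.021, -0.024 and -0.026.

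With only the groups compared, the counts were 4523 for RAF at 26 h, 145 and 355 for clobetasol in uninduced cells and at 50 h, and 395 for Compound A in uninduced cells. The replicate block over all arrays left every other result on its side of the threshold. Within the groups compared, the replicate block gave 147, 388 and 286 for clobetasol in uninduced cells, at 26 h and at 50 h, 514 and 2925 for Compound A, 2116 for long against short clobetasol and 5953 for long clobetasol in uninduced cells. Pairing by number was borne out in 4 comparisons only.

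Leaving out uninduced DMSO replicates 1 and 4 gave 5362 for clobetasol in uninduced cells, 3407 for the mean, 4748 by RAF state, 3431 for the F test and 1156 for Compound A. Leaving out 2 and 3 gave 270, 126 by RAF state and 4832 for Compound A. Leaving out 3 and 4 gave 1132 and 681 by RAF state, and 1 and 2 gave 1236 for Compound A. Leaving out single arrays gave 548 to 3522 for clobetasol in uninduced cells, 170 to 2700 by RAF state, 283 to 1554 for the F test, 438 to 833 at 50 h, 1232 to 3231 and 893 to 1605 for Compound A, 957 to 1880 for its difference from clobetasol at 26 h, and -0.042 to -0.014 for the raised RAF set under clobetasol for 2 h. All other counts stayed within 1.5 times. A set of 3 probes lowered by clobetasol, not described above, changed sides under normexp with Compound A.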

Other observations

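The 8 arrays of clobetasol at 26 h of induction fell into 2 clusters of 4 by the correlation of their deviations from the group mean, which ran from 0.10 to 0.30 over 12 pairs within a cluster and from -0.47 to -0.25 over 16 pairs between them. Replicates 1, 4, 5 and 7 formed a cluster, and replicates 2, 3, 6 and 8 the other.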
